A study of environmental samples with 49 samples.

How the data were processed

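The samples were DNA from soil plots at 3 locations, the Falkland Islands (52 degrees south), Signy Island (60 degrees south) and Anchorage Island (67 degrees south). At each location the plots lay in densely vegetated soil or in bare fell-field soil, and were either left as controls or warmed with open-top chambers, small open enclosures that raise the temperature of the soil inside. Per the labels' protocols, nucleic acids were extracted from soil subsamples by bead beating and phenol-chloroform, the extracts of 1 plot were pooled, and the DNA was amplified across the whole genome and labelled with Cy5. It was hybridised to GeoChip 2.0, a glass array of oligonucleotide probes for microbial genes of nutrient cycling, metal resistance and degradation of organic compounds. Each array carried 1 colour and no reference sample. The replicates were plots as the labels number them, and the number of arrays limits the precision.

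The deposited files are scanner outputs with 1 fluorescence intensity per spot (signal mean, signal median, background mean, background median and background SD), not normalized, per the file headers. Scanner settings other than those in the headers are not given in the sources used here. The other columns used, the flags, grid positions and spot coordinates, were used as the authors deposited them. Per the file headers the spots were read with version 6.1.0 of the spot-reading software on 32 arrays and with version 8.0.0 on 17 arrays. All 17 were controls, and all 24 warmed arrays were read with version 6.1.0. The scan days, taken from the deposited files, were 5 and fell in 2 seasons. All warmed arrays belonged to the second season, and so did 2 of the 25 control arrays, both from Anchorage fell-field soil.

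Each array held 27648 spots, of which 24559 named a probe (24513 different identifiers). The files do not pair identifiers with genes. Of the identifiers, 23663 were a sequence number with a position, and only those of nirK, nifH and amoA named a gene used in a list fixed before the data were examined. The planned gene families, groups of at least 3 probes with 1 gene name, were therefore replaced by probes, as the plan provided. The planned share of each family in the total signal was not computed. One Falkland vegetated control array (replicate 7) carried no identifiers and took those of the other arrays by grid position. Spots named differently on replicate 9 of that group were set to missing.

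Background was corrected with normexp (offset 50) on the signal mean and background median of all spots. Control spots were then removed, log2 values were quantile normalized, spots with a poor flag were set to missing, and spots of 1 probe were averaged. A spot was detected where the signal mean exceeded the background mean by at least 2 background SDs and the spot had no flag. The reading software flags spots as empty below a threshold, which per the file headers was 0.9 on 4 arrays (Falkland vegetated warmed replicates 1 and 3, Anchorage vegetated warmed replicates 2 and 6) and 2 on the others. Over all arrays 0 probe spots past the detection ratio carried that flag, so it did not alter detection, while 1632 carried the poor flag. Those 1632 count as not detected, and no alternative kept them. Most control arrays held more spots with a poor flag than any warmed array, and the effect of this on detection was not tested. Probes detected on at least 3 arrays were tested, 526 in all. One group-means model over all 49 arrays was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The rule for named probes, written before the data were examined, took the 3 with the largest change each way among the called in each comparison. Because the files do not pair identifiers with genes, at most 2 each way are printed. They are printed for 3 comparisons only (the warming mean, warming at Anchorage and soil type on Signy), and these 3 were picked after all counts and alternatives had been seen. Outlying arrays were looked for in the numbers of detected probes and in the levels of these probes alone.

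Detected probes per array were compared by exact permutation tests of the difference of means, and over all 5 environments by 100000 permutations within environments. Composition was tested with a permutational multivariate test (adonis2) in vegan 2.7.1 (Bray-Curtis distance on log2 levels minus the log2 of the offset, 9999 permutations). Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 read the files, and matplotlib 3.10.9 drew the figures. Mean levels of the nirK, nifH and amoA probes were compared with limma without a detection filter, adjusted over the list alone (3 lists). The other planned lists matched no identifier, and the lists were not tested among locations in fell-field soil.

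The model was tested on simulated levels with 100 probes changed by 1 log2 unit and 100 by 0.5 among 526. For the warming mean it recovered 81 of the larger and 29 of the smaller changes, with 0 false among 110 calls. For soil type at Signy it recovered 17 and 1, with 2 false among 20 calls. The simulated levels held independent normal noise for each probe, without misplaced grids, scan seasons, software versions or differences in array brightness. Their shares of false calls therefore do not carry over to the real arrays.

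The alternatives chosen before the data were examined were median centring, no background correction, signal medians, no detection filter, detection on at least 25 arrays, fits on the compared groups alone, scan day as a random block, scan season as a fixed term, a replicate block, leaving out each replicate, warmed in place of control plots, a stricter detection threshold of 3, detection over the spots named Empty, Jaccard distance, and permutations within 1 season. Chosen after seeing the data were the removal of misplaced spots, defined below, a covariate for the brightness of the 16S spots, their combinations with other settings, the Anchorage warming comparison in the second season alone, the comparisons of locations in warmed plots, and composition among the warmed arrays, also with scan day as a term and on scan day 5 alone. A grid was called compressed where its rows lay under 17.5 pixels apart, and the whole array was left out. Columns 1 to 5 of a grid were called misplaced where the mean correlation of columns 1 to 4 with the median warmed array was under 0.25 of the median correlation of columns 6 to 24. For detected probes and composition, the setting without misplaced spots used columns 6 to 24 of every array. Brightness was the median background-corrected log2 level, before normalization, of the 16S-1100 spots at a single position in column 24 of each grid. Brightness differences of the 16S-1100 spots given below use these spots alone, on all arrays including those with a compressed grid.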

Results

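The 49 arrays formed 11 groups. Falkland vegetated soil had 8 control and 8 warmed arrays, Falkland fell-field soil 3 and 2, Signy vegetated soil 6 and 5, Signy fell-field soil 5 and 2, and Anchorage fell-field soil 3 and 5. Anchorage vegetated soil had 2 warmed arrays and no control array analysed here. The design addresses how 3 years of warming altered the distribution of functional genes in vegetated and bare soils along a gradient of latitude. Signal over background was sparse. Over all arrays 0.603% of the probe spots were detected, against 0.0779% of the spots named Empty, 62.1% of the spots named 16S-1100 and 20.6% of those named 16S-900. The number of detected probes ranged from 9 to 871 per array.

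The placement of the reading grid differed between arrays. On 3 Falkland vegetated control arrays (replicates 3, 4 and 7) the grid rows lay 16.41 to 17.07 pixels apart, against 18.32 to 18.55 on the other arrays. On 9 further control arrays the spots of grid columns 1 to 4 had a mean correlation of -0.027 to 0.018 with the median warmed array, while columns 6 to 24 reached 0.345 to 0.682. On the remaining arrays that mean was at least 0.818 times the value for columns 6 to 24. All 12 arrays were controls, so the probe counts, detected probes and composition of comparisons that use control arrays are also given without these misplaced spots, a setting chosen after seeing the data, under which at most 461 probes were tested.

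**Figure D1:**
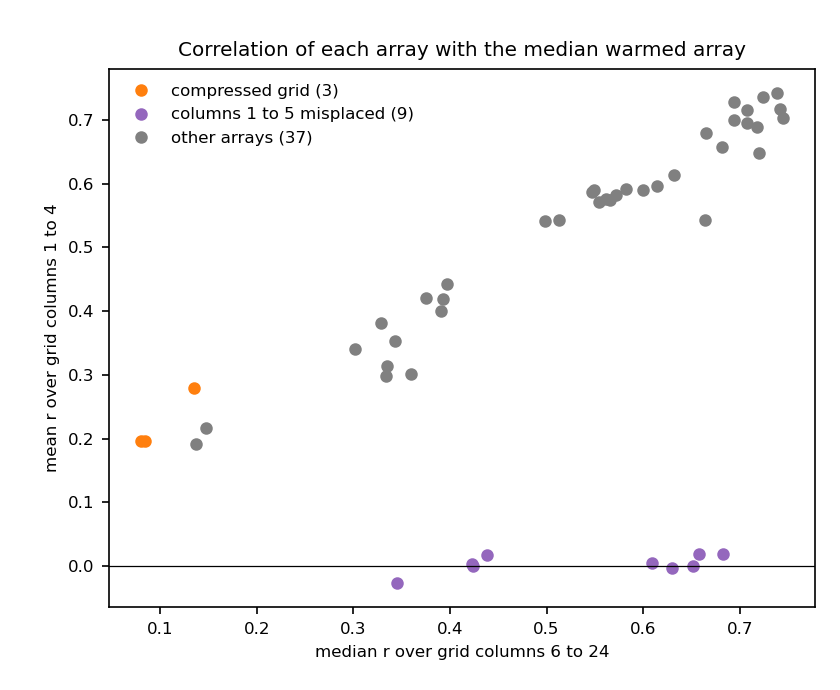
Pearson correlation of each array with the median of the warmed arrays over probe spots, for grid columns 6 to 24 (x axis, median over columns) and grid columns 1 to 4 (y axis, mean over columns); each point is 1 array, coloured by grid placement. The 9 arrays with misplaced columns lie near 0 on the y axis, between -0.027 and 0.018.

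Averaged over the 5 environments with both kinds of plot, 46 probes were higher and 30 lower in warmed than in control plots (76 of 526, limma, adjusted p under 0.05). The rule named 903977_974 (limma adjusted p = 6.82e-05) and 218366_1130, by 2.58 log2 units (SE 0.58, limma adjusted p = 0.00193), as higher in warmed plots. Both lie in grid column 3, whose spots were misplaced on control arrays. Probe 903977_974 was detected on 0 of 3 Falkland and 0 of 5 Signy fell-field control arrays. Its column was misplaced on 2 of these Falkland and 3 of these Signy arrays, and a spot with a poor flag counts as not detected. Non-detection there does not show that its target was absent, and the size of its increase is not given. By the fitted difference the rule also named FW010118B_14 (limma adjusted p = 0.00109) and 34419202_602 (limma adjusted p = 0.0149) as lower in warmed plots. The former was detected on Signy control arrays alone (4 fell-field and 2 vegetated), the latter on 3 vegetated and 1 fell-field control array from Falkland, and neither on a warmed array, so the size of the decrease is not given. Without misplaced spots 60 probes were called, 6 higher and 54 lower, and 29 were called the same way in both fits. The difference of 218366_1130 was then 0.21 (limma adjusted p = 0.638) and FW010118B_14 stayed called (limma adjusted p = 0.000979). Probe 34419202_602 was not tested then, since it was left with fewer than 3 detections. It lies in grid column 21, so most of its vegetated detections came from control arrays with a compressed grid. Its lower level in warmed plots is therefore not settled. The mean of 903977_974 could not be estimated then, since a fell-field control group kept no value of it. Its difference went from 3.14 to 0.06 (limma adjusted p = 0.927) in Falkland vegetated and from 4.26 to 1.91 (limma adjusted p = 0.0181) in Signy vegetated soil. With median centring 20 probes were higher and 53 lower, and that scaling shifted the median of the tested probes by -0.27. By limma 0 probes were called with scan day as a random block (37 at an unadjusted p under 0.05) and 0 with scan season as a fixed term (24), against 156 at an unadjusted p under 0.05 without these terms. The season term rests on Anchorage fell-field control 1 against controls 2 and 4, since no other group had arrays in both seasons. That fit therefore decides little, and the warming mean and the scan season cannot be told apart in these arrays.

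In Anchorage fell-field soil nearly every called probe was higher in the warmed plots, 46 of 47. Probe 17298107_366 stood at 12.31 ± 0.32 (SD, n = 5) in warmed and 8.05 ± 0.68 (SD, n = 3) in control plots (limma adjusted p = 0.000247). It lies in grid column 2, which was misplaced on control 1. Without misplaced spots it stood at 12.21 ± 0.32 (SD, n = 5) and 8.43 ± 0.25 (SD, n = 2), with a limma adjusted p of 0.00125. Probe 38004625_632 stood at 12.97 ± 0.30 (SD, n = 5) and 8.86 ± 0.70 (SD, n = 3), with a limma adjusted p of 1.24e-05. Both were detected on 5 of 5 warmed and 0 of 3 control arrays, so the control level is not above background and the size of the increase is not given. Only 34391466_117 was lower, at 9.66 ± 0.43 (SD, n = 4) against 11.38 ± 1.02 (SD, n = 3), with a limma adjusted p of 0.0338. It was detected on 0 of 5 warmed and 2 of 3 control arrays. The warmed array without a value, set to missing for a poor flag, counts as not detected here. On the 4 warmed arrays with a value its level is not above background. That call was lost with median centring, without a detection filter, with scan day or replicates as a block, and without control 2 (limma adjusted p = 0.193), control 4 (0.128), warmed 3 (0.0649) or warmed 6 (0.0773). Among the arrays of the second season alone (2 control and 5 warmed), 42 probes were called, 41 of them higher. Without misplaced spots 63 probes were higher and 3 lower. Control and warmed arrays of that season were scanned on different days and read with different software versions, and with scan day as a random block 4 probes were called. The 16S-1100 spots were also brighter in the warmed plots, by 1.28 log2 units (exact permutation test, two-sided p = 0.0536).

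In Falkland vegetated soil, where both kinds of plot were read with the same software version, 43 probes were higher and 40 lower under warming. Without misplaced spots, which left 5 control arrays, 18 were higher and 108 lower, and median centring gave 2 higher and 68 lower. The 16S-1100 spots were dimmer in the warmed plots by 1.79 log2 units (10.56 ± 0.51, SD, n = 8, against 12.34 ± 1.06, SD, n = 8; exact permutation test, two-sided p = 0.00155). With that brightness as a covariate 6 probes were called, 5 of them higher. Both the brightness and this fit include the 3 control arrays with a compressed grid. In Falkland fell-field soil 2 probes were higher and 7 lower, against 5 and 73 without misplaced spots and 1 and 85 with median centring.

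In Signy vegetated soil 28 probes were higher and 15 lower under warming, and 20 were higher and 15 lower without misplaced spots. In Signy fell-field soil 7 were higher and 30 lower, against 9 and 55 without misplaced spots and 3 and 76 with median centring. Scan day as a random block left 1 called probe in Signy vegetated, 5 in Signy fell-field, 0 in Falkland vegetated (46 at an unadjusted p under 0.05, limma) and 0 in Falkland fell-field soil (71). The warmed minus control difference varied between the 5 environments for 129 probes (limma F test), and for 252 probes without misplaced spots. That count was 15 with scan day as a random block, 33 with a replicate block and 1 among the 57 probes detected on at least 25 arrays. Season, scan day and software version separated control from warmed arrays in ways that varied between environments. Differing warming effects therefore cannot be told apart from differing technical shifts.

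**Figure D2:**
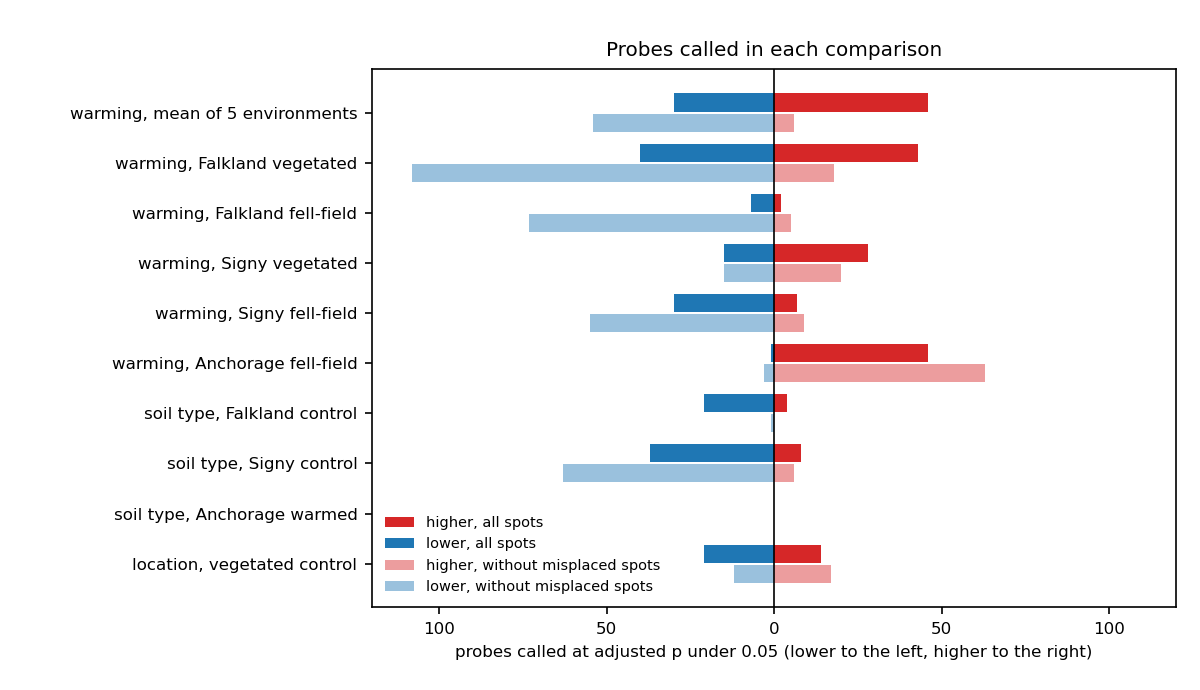
Number of probes called at an adjusted p under 0.05 by limma in each comparison (x axis, counts of probes; lower to the left of 0, higher to the right), with all spots (dark bars) and without misplaced spots (light bars). Averaged over environments, 46 probes were higher and 30 lower with warming when all spots were used, against 6 and 54 without misplaced spots.

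Vegetated and fell-field soils differed most clearly in the control plots on Signy, whose arrays were all scanned on 1 day and read with 1 software version. There 8 probes were higher and 37 lower in vegetated soil. Probe 16761996_478 stood at 11.00 ± 2.25 (SD, n = 5) in vegetated and 7.52 ± 0.94 (SD, n = 5) in fell-field soil (limma adjusted p = 0.00136). Probe 15792851_758 stood at 10.14 ± 1.24 (SD, n = 6) and 7.16 ± 0.51 (SD, n = 5), with a limma adjusted p of 0.00012. It lies in grid column 5, which was misplaced on 3 of the 6 vegetated and 3 of the 5 fell-field arrays, and was not tested without misplaced spots. Both probes were detected on 0 of 5 fell-field arrays, and on 3 and 2 of the 6 vegetated ones, so their fell-field levels are not above background. Probe 32475631_3 was lower in vegetated soil, at 8.79 ± 0.69 (SD, n = 6) against 11.56 ± 0.84 (SD, n = 5), with a limma adjusted p of 0.00361. Probe 37731823_1457 was lower, at 8.89 ± 1.02 (SD, n = 6) against 11.57 ± 0.62 (SD, n = 5), with a limma adjusted p of 0.0031. These were each detected on 5 of 5 fell-field and 1 of 6 vegetated arrays. Without misplaced spots 6 probes were higher and 63 lower, and 36 were lower in both fits. The 16S-1100 spots were dimmer in vegetated soil (10.16 ± 1.65, SD, n = 6, against 12.48 ± 0.60, SD, n = 5; exact permutation test, two-sided p = 0.0303), and with that brightness as a covariate 2 probes were higher and 10 lower. Median centring gave 8 higher and 144 lower, and in the warmed plots 4 were higher and 6 lower.

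In the Falkland control plots 4 probes were higher and 21 lower in vegetated soil. The arrays of the 2 soils were read with different software versions, and without misplaced spots 1 probe was called. In the warmed plots on Anchorage, limma called 0 of 526 probes between 2 vegetated and 5 fell-field arrays, with 13 at an unadjusted p under 0.05. The signal median gave 1 call there, as did the fit on the compared groups alone. Without a detection filter 16 of 24508 probes were called, and without misplaced spots and with scan season 9 of 461.

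Between locations, 14 probes were higher and 21 lower in Falkland than in Signy vegetated control soil. The Falkland arrays were read with version 6.1.0 and the Signy arrays with version 8.0.0, on different scan days, so location cannot be told apart from version and scan day here. Without misplaced spots 17 were higher and 12 lower, with 14 called the same way in both fits. Median centring gave 25 higher and 13 lower, and scan day as a random block called 0 (18 at an unadjusted p under 0.05, limma). The 16S-1100 spots were brighter in the Falkland arrays by 2.18 log2 units (exact permutation test, two-sided p = 0.0157), and with that brightness as a covariate limma called 0 probes in place of 35 (58 in place of 125 at an unadjusted p under 0.05). In fell-field control soil 5 probes differed among the 3 locations (limma F test), and 59 did so without misplaced spots. Location largely coincides with scan day there, and scan day as a random block called 0 (45 at an unadjusted p under 0.05, limma). In the warmed fell-field plots, all read with version 6.1.0, 98 probes differed among locations, but all Anchorage arrays were scanned on a day of their own and location largely coincides with scan day. In warmed vegetated plots, scanned on 1 day, 10 probes were lower on Signy than on Anchorage and 0 were higher.

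The number of detected probes was lower in warmed than in control plots in 4 of the 5 environments. Falkland vegetated soil had 29.0 ± 12.4 (SD, n = 8) detected probes in warmed and 212.5 ± 269 (SD, n = 8) in control plots (exact permutation test, two-sided p = 0.000155, the smallest it can give). Without control replicate 6 the difference moved from -183.5 to -89.4 (exact p = 0.000155). The lowest control array held 71 and the highest warmed array 49. Signy fell-field soil had 49.5 ± 27.6 (SD, n = 2) against 340.0 ± 125 (SD, n = 5), with an exact p of 0.0476, the smallest possible. Falkland fell-field soil had 30.5 ± 30.4 (SD, n = 2) against 330 ± 108 (SD, n = 3), where an exact test cannot go below p = 0.1. Signy vegetated soil had 84.6 ± 23.4 (SD, n = 5) against 147 ± 97.3 (SD, n = 6), with an exact p of 0.143, and the difference moved from -62.2 to -23.6 without control replicate 1. Anchorage fell-field soil went the other way, with 146.0 ± 29.9 (SD, n = 5) in warmed and 79.7 ± 31.9 (SD, n = 3) in control plots (exact p = 0.0536). The mean difference over the 5 environments was -154 probes (permutation test within environments, two-sided p = 0.00036). Without misplaced spots it was -133 (permutation p = 0.00016), with differences of -206 in Falkland vegetated, -231 in Falkland fell-field, -43.2 in Signy vegetated, -238 in Signy fell-field and 53.1 in Anchorage fell-field soil. The 16S-1100 spots were dimmer in the warmed plots, where fewer probes were detected, by 1.79 log2 units in Falkland vegetated soil (exact p = 0.00155), and their difference was -2.57 in Falkland fell-field (exact p = 0.2) and -0.40 in Signy fell-field soil (exact p = 0.476). They were brighter at Anchorage, by 1.28 (exact p = 0.0536), and in Signy vegetated soil, by 0.50 (exact p = 0.522). Median signal-to-noise ratios of the Empty spots were 0.611 to 0.734 with version 8.0.0 and -0.017 to 0.024 with version 6.1.0. Counted over the Empty spots and without misplaced spots, the mean difference was -89.8 (permutation p = 0.00132), that of Signy fell-field soil lost its call at exact p = 0.0952, that of Signy vegetated soil was -9.97, and Anchorage passed the threshold with a difference of 74.8 (exact p = 0.0179).

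**Figure D3:**
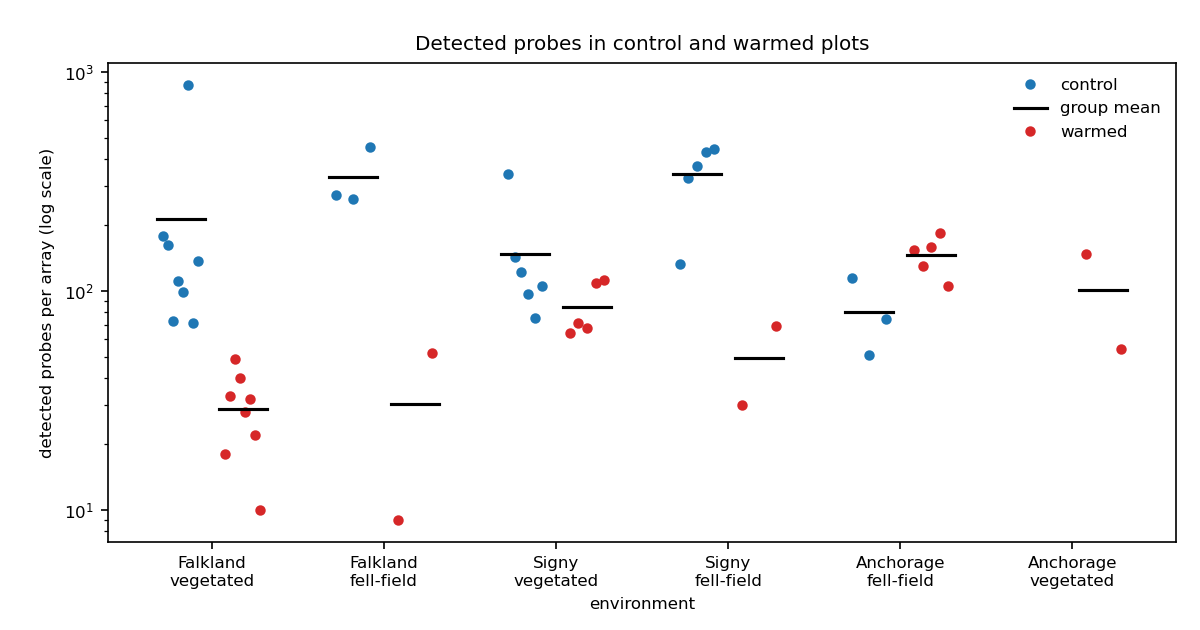
Detected probes per array (y axis, log scale) by environment (x axis), in control (blue) and warmed (red) plots; points are arrays and black lines group means. All 8 warmed arrays of Falkland vegetated soil lie below the 8 control arrays, while in Anchorage fell-field soil the warmed mean of 146.0 lies above the control mean of 79.7.

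Vegetated control soil held fewer detected probes than fell-field control soil on Signy, with a difference of -193 (exact permutation test, two-sided p = 0.026), and of -173 (exact p = 0.0108) without misplaced spots. The call was lost without fell-field control 3 (-186), 4 (-171) or 5 (-167). Array brightness was also lower in vegetated control soil on Signy, at 10.16 against 12.48 (exact permutation test, two-sided p = 0.0303). It therefore stays open as a source of the lower number of detected probes there, and its part was not tested. On the Falkland Islands the difference in detected probes was -118 (exact p = 0.57). It was -27.8 without misplaced spots, -23.3 over the Empty spots and 50.9 with both (exact p = 0.982), so its direction is not settled. Leaving out vegetated control replicate 6, the array with 871 detected probes, gave -212 (exact p = 0.00833), and leaving out fell-field control replicate 3 gave -55.5.

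Environment accounted for 15.6% of the variance in composition (permutational multivariate test, 47 arrays, permutation p = 0.0037) and warming within environments for 7.62% (permutation p = 0.0004). Without misplaced spots (44 arrays) these shares were 15.9% (permutation p = 0.0083) and 6.30% (permutation p = 0.0124). All warmed arrays and only 2 of the 25 control arrays belonged to the second season, so the share of warming cannot be told apart from that of scan season. Among the 22 warmed arrays alone, environment accounted for 42.3% (permutation p = 0.0011). These arrays share a season and a software version but lie on 3 scan days. Tests within scan days were chosen after seeing the data. With scan day as a first term and permutations within days, environment accounted for a further 21.6% (permutation p = 0.0006). On scan day 5 alone, the difference between Signy vegetated and Anchorage fell-field soil accounted for 38.3% of the variance of 10 arrays (exact p = 0.00794 over 252 splits, the smallest possible). The Signy arrays there held 84.6 detected probes on average and the Anchorage arrays 146.0, with mean 16S-1100 levels of 10.67 and 11.39. Array brightness therefore stays open as a source of these shares among warmed arrays, and its part was not tested. Within the second season at Anchorage, the split into 2 control and 5 warmed arrays accounted for 56.8% of the variance of 7 arrays (exact p = 0.0476 over 21 splits, the smallest possible). The same split separates scan day 4 from scan day 5 and version 8.0.0 from version 6.1.0, so warming cannot be told apart from these.

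Probes named for nirK, a copper nitrite reductase of denitrification, for nifH, the nitrogenase iron protein, and for amoA, a subunit of ammonia monooxygenase, gave almost no signal above background. Of the spot readings, 7 of 6762 were detected for nirK, 4 of 735 for amoA and 0 for nifH, which had 17 spots on each of the 49 arrays. The mean nifH level was 0.11 log2 units higher in warmed plots over the 5 environments (limma, adjusted p = 0.0265 over the 3 lists), at readings that were all below the detection limit, and with scan day as a random block the adjusted p was 0.519. With scan season as a fixed term the difference turned to -0.08, and to -0.07 also without misplaced spots. Both values rest on a season term set by the Anchorage fell-field controls alone, so they decide little. The call was lost without Anchorage fell-field control 1 (limma adjusted p = 0.0711) or 4 (0.0554), Falkland fell-field warmed 3 (0.14) or Signy fell-field warmed 2 (0.0582). The nirK and amoA levels differed by 0.05 (adjusted p = 0.109) and 0.02 (adjusted p = 0.77). In the soil type comparison on Signy, nifH differed by 0.15 (adjusted p = 0.144), nirK by 0.07 (adjusted p = 0.208) and amoA by -0.06 (adjusted p = 0.559). No list passed the threshold in the other soil type comparisons or between Falkland and Signy vegetated soil.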

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

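The tests of software version, of scan season and of misplaced columns at Signy were chosen after the results were seen, as were the setting without misplaced spots, the 16S covariate and a second condition in the test of array brightness.

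Several arrays stood apart from their group. Falkland vegetated control replicate 6 held 871 detected probes, against a median of 111 on the other arrays of its group. Signy vegetated control replicate 1 held 340, against a median of 105. The level of probe 903977_974 was 14.58 on Anchorage fell-field warmed replicate 6, against 15.27 on each other array of its group. Quantile normalization gives such tied values to spots of equal rank, so any array with another rank there would be flagged. The level of probe 218366_1130 was 7.19 on Falkland vegetated control replicate 7, an array with a compressed grid, against a median of 13.01. On Falkland vegetated warmed replicate 9 it was 11.06, against a median of 12.89. Such a gap arises by chance in about 1 in 20 groups, and 40 groups were tested. That rate does not apply to tied values, as those of 903977_974.

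The warmed minus control difference varied between environments for 129 probes by the F test, which cannot tell differing warming effects from differing shifts of season, scan day or version. Of the 30 spots named Blank, which the comparisons do not use, 18 were detected on Falkland fell-field control replicate 3. Of the 9 arrays with misplaced columns 4 detected a Blank spot, and none of the 37 arrays without a misplaced grid did.

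More probes were called higher than lower in the mean over environments, 46 against 30. Misplaced grid columns are a candidate explanation, since they would give control arrays wrong readings in columns 1 to 5. Of the probes called higher, 82.6% lay in these columns, against 15.6% of the other tested probes (Fisher's exact test, one-sided p = 1e-20). Without misplaced spots 6 probes were higher and 54 lower. Relabelling control and warmed arrays within environments argues against chance as the source of the 76 calls. Only 1 of 100 draws, the real one, gave as many, and the highest other gave 21. Scan season stays open, and so does warming, because nearly all control arrays lay in another season than the warmed ones. The fit with scan season called no probe, but its season term rests on the Anchorage fell-field controls alone and decides little.

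Fewer probes were detected in warmed than in control plots outside Anchorage. Software version alone cannot account for the Falkland vegetated part, because both kinds of array were read there with 1 version and the difference without misplaced spots was -206 (exact permutation test, p = 0.000777, the smallest possible). Of the bounds written for this test both were met, since the difference is also smaller than the control SD of 252. The exact test was taken to decide because 1 array with 675 detected probes widens that SD and the lowest control array, with 76, lies above the highest warmed one, with 36. In the other environments version and warming coincide. In Anchorage fell-field soil, the warmed minus control difference within the second season was 83.5 (exact p = 0.0476, the smallest possible). It decides nothing about season, since Anchorage showed no decrease over both seasons either (66.3), and the bound first written for it, rewritten after this value was seen, had overlooked that. Scan season and warming cannot be told apart as the source of the decrease, since 0 other environments had both kinds of plot in 1 season. Array brightness stays open too, because the 16S-1100 spots changed the same way as the detected probes in 4 of the 5 environments, Signy vegetated soil being the exception. The warming differences at Anchorage and in Falkland vegetated soil were 250 probes apart (permutation p = 0.149), and 281 apart (permutation p = 0.00832) over the Empty spots and without misplaced spots. With all spots the control SDs there were 31.9 and 269, and the warmed means 146.0 and 29.0. A permutation test takes the exchanged arrays as alike in level and spread. These p-values therefore do not decide whether the warming differences themselves differ.

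Most probes called between soil types in the Signy control plots were lower in vegetated soil. Misplaced columns are not the source, since 36 of the 37 probes called lower and still tested stayed called lower without misplaced spots. Array brightness stays open as a possible explanation. Of 63 probes called lower without misplaced spots, 10 stayed called with the 16S covariate, which meets the bound set in advance for brightness as the cause. Yet the median difference of these probes moved only from -1.65 to -1.54 while the median SE rose from 0.45 to 0.55, so the calls ended mainly through the wider error. The condition on the median was added after these values were seen, and without it the verdict would be that brightness accounts for the calls. A difference between soils remains among the open explanations.

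Other splits of the same arrays were fitted for each comparison of at least 3 arrays per group, with all spots, misplaced ones included. For warming in Falkland vegetated soil, 3 of 100 splits, the real one included, gave as many calls as the real 83, under the bound written in advance. The highest other split there gave 154, so chance is not excluded. No other split fitted gave as many calls for warming in Signy vegetated soil (43 calls, 1 of 100, highest other 13) or Anchorage fell-field soil (47 calls, 1 of 56, highest other 2). The same held for soil type on Signy (45 calls, 1 of 100, highest other 35). These splits argue against chance for these 3 comparisons, with all spots used. Chance cannot be excluded for soil type in Falkland control plots (25 calls, 15 of 100), where the highest other split gave 309 and points to a structure of these arrays. Nor can it be excluded for location in vegetated control soil (35 calls, 11 of 100, highest other 149) or in fell-field control soil (5 calls, 23 of 100, highest other 49).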

How the results depend on the processing

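The removal of misplaced spots, the 16S covariate, their combinations, the comparisons of locations in warmed plots and those of composition within scan days were chosen after seeing the data. Counts are of called probes, and those given are the ones beyond 1.5 times the count in the report. Of 455 values under alternatives other than leaving out an array, 308 kept their direction and their side of the threshold or stayed within that bound. Except where stated, the cause was not tested.

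With median centring, the count was 86 for warming in Falkland fell-field soil, 27 for warming in Signy vegetated soil, 79 for warming in Signy fell-field soil, 73 for warming at Anchorage, 242 for the differing warming effects and 110 for soil type on Falkland, and 152 for soil type on Signy and 124 for location in fell-field soil. Without background correction, the count was 30 for warming in Falkland fell-field soil, 72 for warming in Signy fell-field soil, 78 for soil type on Falkland, 79 for soil type on Signy and 55 for location in fell-field soil. With signal medians, the count was 1 for soil type on Falkland, 1 for soil type on Anchorage and 9 for location in fell-field soil. Without a detection filter, the count was 28 for warming in Falkland fell-field soil, 81 for warming in Signy vegetated soil, 95 for warming in Signy fell-field soil, 250 for the differing warming effects, 1 for soil type on Falkland and 16 for soil type on Anchorage, and 91 for location in vegetated soil and 8 for location in fell-field soil. For probes detected on at least 25 arrays, of which 57 were tested, the count was 9 for the warming mean, 18 for warming in Falkland vegetated soil, 2 for warming in Falkland fell-field soil, 4 for warming in Signy vegetated soil, 0 for warming in Signy fell-field soil and 0 for warming at Anchorage. There it was also 1 for the differing warming effects, 10 for soil type on Falkland, 0 for soil type on Signy, 4 for location in vegetated soil and 0 for location in fell-field soil. In fits on the compared groups alone, the count was 17 for warming in Falkland vegetated soil, 0 for warming in Falkland fell-field soil, 112 for warming at Anchorage, 0 for soil type on Falkland, 1 for soil type on Anchorage and 1 for location in vegetated soil, and 24 for location in fell-field soil. With scan day as a random block, the count was 0 for the warming mean, 0 for warming in Falkland vegetated soil, 0 for warming in Falkland fell-field soil, 1 for warming in Signy vegetated soil, 5 for warming in Signy fell-field soil and 4 for warming at Anchorage. There it was also 15 for the differing warming effects, 0 for location in vegetated soil and 0 for location in fell-field soil. With scan season as a fixed term, the count was 0 for the warming mean, 8 for warming in Falkland vegetated soil, 0 for warming in Falkland fell-field soil, 1 for warming in Signy vegetated soil, 0 for warming in Signy fell-field soil and 8 for location in fell-field soil. Without misplaced spots, the count was 126 for warming in Falkland vegetated soil, 78 for warming in Falkland fell-field soil, 64 for warming in Signy fell-field soil, 252 for the differing warming effects, 1 for soil type on Falkland and 69 for soil type on Signy, and 59 for location in fell-field soil. Without misplaced spots and with scan season, the count was 1 for the warming mean, 7 for warming in Falkland vegetated soil, 3 for warming in Falkland fell-field soil, 2 for warming in Signy vegetated soil, 12 for warming in Signy fell-field soil and 96 for warming at Anchorage. There it was also 1 for soil type on Falkland, 77 for soil type on Signy, 9 for soil type on Anchorage and 16 for location in fell-field soil. With the 16S covariate, the count was 6 for warming in Falkland vegetated soil, 3 for warming in Falkland fell-field soil, 27 for warming in Signy vegetated soil, 72 for the differing warming effects, 12 for soil type on Signy and 0 for location in vegetated soil, and 3 for location in fell-field soil. Without misplaced spots and with the 16S covariate, the count was 35 for the warming mean, 31 for warming in Falkland vegetated soil, 32 for warming in Falkland fell-field soil, 25 for warming in Signy vegetated soil, 59 for warming in Signy fell-field soil and 1 for soil type on Falkland. There it was also 10 for soil type on Signy, 10 for location in vegetated soil and 10 for location in fell-field soil. In warmed in place of control plots, the count was 3 for soil type on Falkland and 10 for soil type on Signy. Between Signy and Anchorage in warmed plots, the count was 10 for location in vegetated soil. In warmed fell-field plots, the count was 98 for location in fell-field soil. With a replicate block, the count was 5 for warming in Falkland fell-field soil, 28 for warming in Signy vegetated soil, 9 for warming at Anchorage and 33 for the differing warming effects.

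With scan season, the difference of probe 903977_974 in the warming mean was -1.36, that of 218366_1130 -1.57 and that of FW010118B_14 0.0071. It was 0.013 for FW010118B_14 also without misplaced spots. The season term rests on Anchorage fell-field control 1 against controls 2 and 4 alone. Columns 1 to 5 of control 1 were misplaced, and 903977_974 and 218366_1130 lie in column 3, so their turned differences decide nothing. Of 380 values of named probes, here with the fits without 1 array included, 357 kept direction and call, 19 lost the call and 4 turned. Most of the 380 come from leaving out 1 array, so the share kept says little about the other alternatives.

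Replicate numbers gave 20 pairs of a control and a warmed array, with correlations of -0.15 to 0.11, of which 1 exceeded 0.1, and 2 arrays matched best with their own number. Such low correlations do not decide whether the numbers pair the plots, since control and warmed arrays also differed in scan day and mostly in season. The replicate block over 40 arrays is given as an alternative only.

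Counted over the Empty spots, the difference in detected probes at Anchorage was 93.7 (exact p = 0.0179). Over these and without misplaced spots it was 74.8 (exact p = 0.0179) at Anchorage, -155 (exact p = 0.0952) in Signy fell-field soil and 50.9 (exact p = 0.982) between Falkland soils.

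With median centring, the list difference was 0.074 for nirK in the warming mean (limma adjusted p = 0.0132), 0.20 for nifH in soil type on Signy (limma adjusted p = 0.0207), 0.013 for nirK in location in vegetated soil and 0.023 for nifH in location in vegetated soil. Without background correction, the list difference was -0.0093 for amoA in the warming mean and 0.012 for nirK in soil type on Falkland. With signal medians, the list difference was 0.061 for nirK in the warming mean (limma adjusted p = 0.0166), 0.017 for nirK in location in vegetated soil and 0.056 for nifH in location in vegetated soil. With scan day as a random block, the list difference was 0.082 for nifH in the warming mean (limma adjusted p = 0.519). With scan season as a fixed term, the list difference was -0.022 for nirK in the warming mean, -0.077 for nifH in the warming mean and -0.052 for amoA in the warming mean. Without misplaced spots, the list difference was -0.090 for amoA in soil type on Falkland, 0.0085 for nirK in location in vegetated soil and -0.073 for amoA in location in vegetated soil. Without misplaced spots and with scan season, the list difference was -0.021 for nirK in the warming mean, -0.074 for nifH in the warming mean, -0.014 for amoA in the warming mean, -0.090 for amoA in soil type on Falkland, 0.0085 for nirK in location in vegetated soil and -0.073 for amoA in location in vegetated soil. With the 16S covariate, the list difference was 0.011 for nirK in location in vegetated soil. Without misplaced spots and with the 16S covariate, the list difference was -0.094 for amoA in soil type on Falkland, 0.011 for nirK in location in vegetated soil and -0.061 for amoA in location in vegetated soil. None of the turned list differences was past the threshold in the alternative.

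For the warming mean leaving out 1 array gave 47 to 85, past 1.5 times for Anchorage fell-field control 1 (47) and Signy fell-field warmed 3 (50). For warming in Falkland vegetated soil leaving out 1 array gave 65 to 92. For the differing warming effects leaving out 1 array gave 104 to 183. For soil type on Falkland leaving out 1 array gave 1 to 52, past 1.5 times for Falkland vegetated control 1 (48), 2 (43), 3 (1), 4 (1), 6 (52), 7 (1) and 9 (45) and Falkland fell-field control 2 (4) and 3 (1). For location in vegetated soil leaving out 1 array gave 10 to 61, past 1.5 times for Falkland vegetated control 4 (19) and 6 (61) and Signy vegetated control 1 (17), 2 (10), 4 (20), 5 (17) and 6 (16). For warming in Falkland fell-field soil leaving out 1 array gave 1 to 46, past 1.5 times for Falkland fell-field control 1 (1), 2 (15) and 3 (5) and Falkland fell-field warmed 1 (2) and 3 (46). For location in fell-field soil leaving out 1 array gave 0 to 21, past 1.5 times for Falkland fell-field control 1 (0) and 2 (21), Signy fell-field control 1 (17) and 4 (9) and Anchorage fell-field control 1 (14), 2 (1) and 4 (3). For warming in Signy fell-field soil leaving out 1 array gave 6 to 54, past 1.5 times for Signy fell-field warmed 2 (8) and 3 (6). For soil type on Signy leaving out 1 array gave 26 to 45, past 1.5 times for Signy fell-field control 3 (28) and Signy vegetated control 4 (26) and 6 (26). For warming in Signy vegetated soil leaving out 1 array gave 17 to 46, past 1.5 times for Signy vegetated control 1 (25), 2 (24) and 6 (21) and Signy vegetated warmed 2 (22), 3 (22), 5 (17) and 6 (28). For warming at Anchorage leaving out 1 array gave 19 to 42, past 1.5 times for Anchorage fell-field control 2 (21) and 4 (19) and Anchorage fell-field warmed 2 (29), 3 (26), 4 (25) and 6 (31). For soil type on Anchorage leaving out 1 array gave 0 to 0. Where 1 array was left in a group, it is assumed to vary like the other groups.

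Leaving out 1 array gave list differences of 0.023 to 0.068 for nirK in the warming mean, 0.079 to 0.14 for nifH in the warming mean, -0.011 to 0.045 for amoA in the warming mean, -0.058 to 0.018 for nirK in soil type on Falkland, -0.022 to 0.022 for nirK in location in vegetated soil, -0.039 to 0.025 for nifH in location in vegetated soil, -0.010 to 0.042 for nirK in soil type on Anchorage, -0.27 to 0.073 for nifH in soil type on Anchorage and -0.024 to 0.060 for amoA in soil type on Anchorage. The nifH call was lost without Anchorage fell-field control 1 (0.097) or 4 (0.10), Falkland fell-field warmed 3 (0.079) or Signy fell-field warmed 2 (0.094), and nirK was called without the last (0.068).

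For detected probes the range was -204 to -89.4 in Falkland vegetated soil, with -89.4 without control 6, and -76.6 to -23.6 in Signy vegetated soil, with -23.6 without control 1. It was -343 to -265 in Signy fell-field soil, where each of its 7 arrays left out ended the call (without control 1 -343, 2 -294, 3 -283, 4 -269 and 5 -265, without warmed 2 -271 and 3 -310.0), since fewer arrays cannot pass the threshold. It was 52.0 to 83.5 at Anchorage, with a call without control 1 (83.5) or warmed 6 (76.6), and -212 to -55.5 between Falkland soils, with a call without vegetated control 6 (-212) and -55.5 without fell-field control 3. Between Signy soils it was -245 to -167, with the call lost without fell-field control 3 (-186), 4 (-171) or 5 (-167).

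The planned share of each gene family could not be run because the files name no families. With 0.603% of the probe spots detected, signal over background limits all comparisons to few probes.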

Other observations

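The test of the Signy and Falkland correlation and the test of probe pairs below were written before their results were seen, but the reading of the second was changed afterwards, and the setting without misplaced spots was chosen after seeing the data.

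The differences between vegetated and fell-field control soil on Signy and on the Falkland Islands came from separate arrays. Across probes, which are not independent replicates, they correlated at 0.22. A hypothesis is that part of the soil type effect may be shared by the locations. Of 100 splits of the Signy control arrays, the real one included, 97 gave a lower correlation, and the highest other gave 0.24. The arrays of the Falkland soils differed in software version, while those of the Signy soils were all read with the same version. Array brightness was lower in vegetated than in fell-field control soil on Signy (difference -2.32, exact permutation test, two-sided p = 0.0303). On the Falkland Islands its difference was -0.65 (exact p = 0.412). The correlation was not computed with brightness as a covariate, so a technical source of the shared part stays open.

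Another hypothesis was that probes of 1 sequence number, which target the same deposited sequence, may move together. Among the tested probes there were 20 such pairs from 16 sequence numbers. Their soil type differences on Signy correlated at 0.33, close to the 95th percentile of 0.33 among 10000 random sets of pairs, of which 528 were as high. By the bound written in advance, the 95th percentile, the pairs did not move together more than random ones. After the value was seen the reading was changed to undecided, on the ground that 20 pairs are few and the value lies so close to the bound.

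The warmed arrays of Anchorage vegetated soil, which have no control here, held 54 and 147 detected probes. Their 16S-1100 spots stood at 8.95 ± 1.00 (SD, n = 2), against 11.39 ± 0.65 (SD, n = 5) on the warmed fell-field arrays of that island (exact permutation test, two-sided p = 0.0476, the smallest possible).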
